A study of Bradyrhizobium diazoefficiens USDA 110 with 4 samples.

How the data were processed

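Total RNA of chemoautotrophically and heterotrophically grown cells of Bradyrhizobium diazoefficiens was compared on 4 arrays read in 2 colours. Per the labels' protocols, RNA was extracted with hot phenol, copied into cDNA with random hexamers, and coupled to Cy3 or Cy5 after the RNA was digested. The series design names 2 independent biological materials for each growth condition, and each pair of materials was hybridised on 2 arrays with the dyes exchanged. The growth media, the gas phase, the scanner, the background correction, the spot filter, the normalization method and the design of the probes are not given in the sources used here.

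The authors deposited 1 normalized log2 ratio per probe and array, which the labels describe as chemoautotrophy over heterotrophy on every array. As deposited, the 2 arrays of a dye exchange correlated at -0.940 in replicate 1 and at -0.895 in replicate 2 (Pearson's r across 8247 and 8198 probes, which are not independent replicates), so the deposited values of the 2 dye orientations run in opposite directions. The sign of the arrays with chemoautotrophic cDNA in Cy5 was turned, because the titles of the arrays with chemoautotrophic cDNA in Cy3 name chemoautotrophy first, as their descriptions do, while the titles of the other arrays name heterotrophy first. The dyes in the labels do not settle this, and the direction is called likely for that reason. Turning the Cy3 arrays instead mirrors every value.

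The table listed 8480 probes, with 8341 and 8305 values on the arrays of replicate 1 and 8314 and 8243 on those of replicate 2. The medians of the deposited values were -0.09 and 0.07 in replicate 1 and -0.002 and -0.05 in replicate 2, in each case with the Cy3 array first. They were kept without further centring, and how the authors centred and scaled the arrays stays unknown. No spot intensities were used here, so no filter on dim spots and no intensity trend could be applied, the signal behind a ratio is unknown, and the number of arrays limits the precision.

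Probes were named through the platform annotation, which is old and gives 1 symbol for each of 8462 probes and none for the other 18. The probes stood for 8269 loci, of which 1446 had a gene symbol and 6823 a locus tag only. None of the annotation's gene identifiers matched the reference gene table (0 of them), so symbols were not updated and no genome coordinates are given. Loci are given by their tags, whose numbers follow the order of the genes. Several probes of a locus were averaged (191 loci), and at 85 of these the probes differed in sign. Of the 5 such loci that passed the test, 1 (bll2373) had probes of opposite sign. A symbol was shared by 442 loci, and how specific their probes are is not given in the sources used here.

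The arrays of a dye exchange hybridise the same extracts, so their mean counted as 1 replicate and n = 2. A locus needed a value in both replicates, which left 8126 loci tested and 143 out. The mean log2 ratio was tested against 0, two-sided, with limma 3.58.1 (lmFit and eBayes, R 4.3.3), at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all loci tested. The fit had 1 residual degree of freedom per locus and 5.62 prior degrees of freedom, so the moderated errors borrow most of their information from other loci. P-values and each SE given with a log2 ratio rest on these moderated errors. They reflect the spread between the 2 replicates pooled largely over other loci, and not that of the single locus alone. The dye effect cancels in a replicate's mean where both of its arrays measured the locus; 208 of the 8126 loci, 4 of them among those that passed, lacked a value on at least 1 array, and there it does not cancel.

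Before the data were examined, 25 gene lists were fixed by symbol and product words for a soil bacterium growing on hydrogen and carbon dioxide against organic carbon. The annotation holds no product names, so members were matched by symbol alone, and the lists of ABC transporters and insertion sequences had 0 members. The 19 lists with at least 5 measured members were tested with limma's camera, a test of a list against all other loci, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists. Counts of members are given over all loci and adjusted over the list alone. At the preset value 9 of the 19 lists passed. With a correlation estimated from 2 replicates, which leaves 1 residual degree of freedom, 0 did. Such an estimate depends only on how many members were higher in replicate 1 than in replicate 2. It does not measure how far members move together and cannot be set against the preset value. For the hydrogenase list the estimate was -0.008, and the camera adjusted p went from 6.56e-11 to 0.567. With 1 degree of freedom this variant could hardly pass any list, so its values are given without a conclusion.

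The genes named in the text were set by a rule fixed beforehand. It took the 8 highest and 8 lowest loci with a symbol that passed the test with 1 sign on every array, and 3 members per list that passed, or the 2 furthest from 0 where none did. It added cbbL, cbbS, hupL, hupS and cutL, the 3 longest runs of loci changed the same way (ties kept), in which 1 locus that did not pass may lie between members on either strand, and 2 loci in each direction known by tag only. Genes named outside it are given as chosen after their values were seen.

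The procedure was tested on simulated log2 ratios for the 8126 loci, 200 of them changed. It recovered 28.4% of loci changed 2-fold, 100% of those changed 4-fold and 100% of those changed 8-fold, with 18 false calls among 170. The share of false calls was thus larger than the adjusted p threshold of 0.05 aims at. The simulated variances were drawn from the prior fitted to the data, with equal spread in both replicates. The measured replicates had an SD of 0.75 and 0.65 across loci. The recovered shares therefore hold under the test's own model. The procedure called 0 of 20 unshifted lists. The simulated loci were drawn independently of each other. That count therefore cannot show how often camera with the preset correlation calls unshifted lists whose members move together. Alternatives covered the treatment of the dye exchange, a block for the replicate, centring and scaling of the arrays, robust moderation, missing values, thresholds, left-out arrays, the direction and the kind of list test. For the fits on all 4 arrays the correlation within a replicate was 0.681; it could not be estimated beside a dye term, so the same value was used there. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.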

Results

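Transcript levels of Bradyrhizobium diazoefficiens, a soil bacterium that nodulates soybean, were measured in chemoautotrophically grown cells against heterotrophically grown cells on 4 arrays. Chemoautotrophic cells gain energy by oxidising inorganic compounds and build biomass from carbon dioxide, whereas heterotrophic cells live on organic carbon. Each of 2 biological replicates was hybridised in both dye orientations, so each orientation held 2 arrays, 1 per replicate. Between 8243 and 8341 of 8480 probes had a value on an array, and 8126 loci could be tested. The median moderated standard error of a log2 ratio was 0.24, and every SE of a log2 ratio below is moderated across loci. The number of arrays limits the precision.

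The comparison asked which transcripts differ between the 2 modes of growth. Genes of the uptake hydrogenase, which oxidises hydrogen, and of the Calvin cycle, which fixes carbon dioxide, were among the highest in chemoautotrophic cells. hupC (bll6940), for the hydrogenase's cytochrome b subunit, was 35.1-fold higher, at a log2 ratio of chemoautotrophy over heterotrophy of 5.13 ± 0.23 (SE, n = 2). The small hydrogenase subunit gene hupS (bll6942) was 27.9-fold higher (4.80 ± 0.25, SE, n = 2), and cbbL (blr2585), for the large subunit of ribulose bisphosphate carboxylase, 12.7-fold higher (3.67 ± 0.35, SE, n = 2). In the other direction, fixK at bll2757, for a regulator of genes used at low oxygen, was 12.7-fold lower (-3.66 ± 0.23, SE, n = 2). The limma adjusted p was 0.000803 for hupC, 0.00126 for hupS, 0.00547 for cbbL and 0.00145 for fixK.

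These directions are likely rather than settled. The arrays of a dye exchange correlated at -0.940 and -0.895 as deposited, and the sign of the arrays with chemoautotrophic cDNA in Cy5 was turned. Turning the other orientation instead mirrors every value, with 163 loci higher and 195 lower.

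In all, 358 of 8126 loci (4.41%) changed at a limma adjusted p under 0.05, 195 higher and 163 lower in chemoautotrophic cells. Each of the 358 had 1 sign on all arrays that measured it, the smallest change was 2.17-fold and the median 3.37-fold. An unadjusted p under 0.05 was reached by 1559 loci. Of the changed loci 79 carried a gene symbol, 65 of them higher and 14 lower. Symbols stood on 33.3% of the higher and 8.59% of the lower loci (Fisher's exact test, two-sided p = 9.09e-09, across loci that are not independent), against 17.6% of all loci tested. The replicate means correlated at r = 0.610 across loci, which are not independent replicates. Both arrays of each replicate in 1 fit with a replicate block gave 981 changed loci, 356 of them shared with the 358, and centring each array on its median gave 749. Without the Cy3 array of replicate 1 the count was 234, and without the Cy5 array of replicate 2 it was 916, each array being named by the dye of its chemoautotrophic cDNA.

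**Figure D1:**
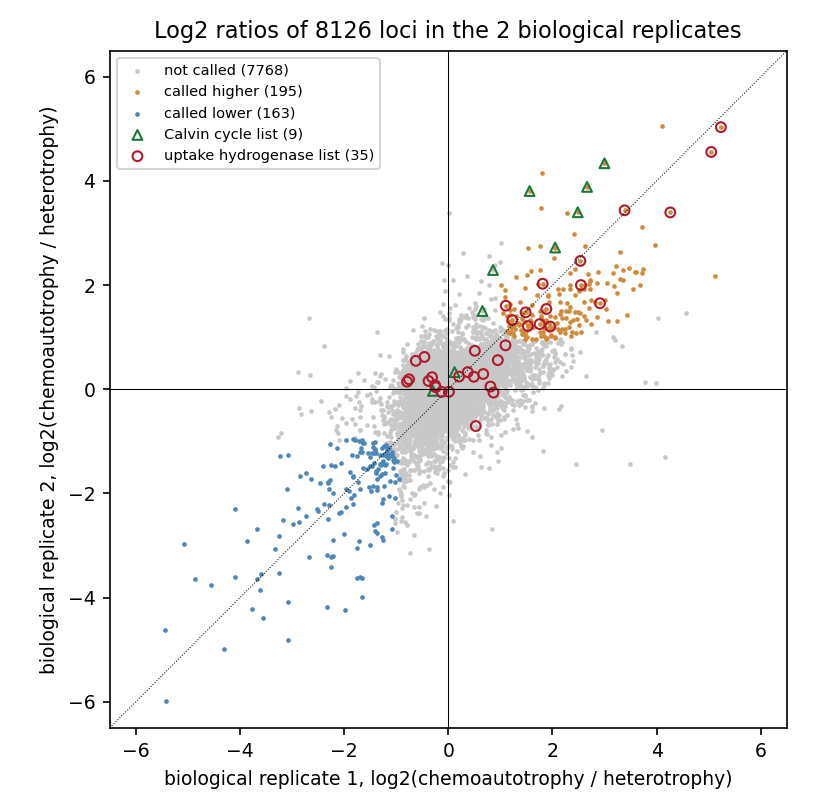
Log2 ratios of chemoautotrophy over heterotrophy (likely direction) of the 8126 tested loci, with replicate 1 on the x axis and replicate 2 on the y axis, each point being the mean of the arrays of a dye exchange. Loci that passed the test are coloured (195 higher, 163 lower), triangles mark the 9 Calvin cycle genes and circles the 35 hydrogenase genes, and the dotted line marks equal ratios.

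Of 35 measured hydrogenase genes, 15 rose and 0 fell in chemoautotrophic cells, and 17 rose when adjusted over the list alone (limma; 18 members had an unadjusted p under 0.05). The list was shifted upward at a camera adjusted p of 6.56e-11 (adjusted p = 0.567 with an estimated correlation). The large subunit gene hupL (bll6941) rose 10.6-fold (3.41 ± 0.23, SE, n = 2) and hupF (bsl6938) 14.2-fold (3.83 ± 0.29, SE, n = 2). The 8 genes from bsl6935 to bll6942, hupI, hupH, hupG, hupF, hupD, hupC, hupL and hupS, all rose, by 1.48 to 5.13 on the log2 scale. Beside them, 7 loci between bll6924 and bll6932 rose by 1.28 to 2.28, while bll6928 (0.52 ± 0.32, and -0.03 without replicate 2) and hypF (bll6930, 0.62 ± 0.23), both named after their values were seen, did not pass (adjusted p 0.466 and 0.212). Among the 7 are hypA (2.27 ± 0.25) and hypB (1.92 ± 0.23), for proteins that supply nickel to the enzyme, and hypC (2.28 ± 0.34), hypE (1.28 ± 0.23) and hoxX (1.37 ± 0.24), all with n = 2. A second set of hydrogenase genes at blr1720 to blr1737 had a median log2 ratio of -0.09 over 11 members, with 0 past the limma test and 1 at an unadjusted p under 0.05. There hupL (blr1721) was at 0.76 ± 0.24 and hupS (blr1720) at 0.43 ± 0.27 (adjusted p 0.151 and 0.499), and this hupL passed with the replicate block (adjusted p = 0.0474). That set alone, chosen after its values were seen, had a camera adjusted p of 0.647, with a positive direction against its negative median. The symbol hupA (bll6175, 2.83-fold higher), which is also used for a DNA-binding protein, counts among the 15 and was singled out after its value was seen. The call of hupG was lost without the Cy3 array of replicate 2 (adjusted p = 0.0528), that of bll6925 without the Cy3 array of either replicate (0.0555 and 0.0631), and that of hypE after quantile normalization. Without replicate 1 hypC was at 1.65, and without replicate 2 at 2.91.

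Of 9 Calvin cycle genes, 5 rose and 0 fell, and 7 rose when adjusted over the list alone (limma; 7 members had an unadjusted p under 0.05). Besides cbbL these were the aldolase gene cbbA (3.28 ± 0.33, 9.68-fold), cbbX (2.94 ± 0.29), for an activase of the carboxylase, the phosphoribulokinase gene cbbP (2.68 ± 0.49) and the small subunit gene cbbS (2.39 ± 0.26, 5.23-fold), all with n = 2. With blr2588 (1.76 ± 0.23) they are the 6 changed loci of a stretch from blr2582 to blr2588 that also holds cbbT (blr2583, 1.57 ± 0.36). cbbT, named after its value was seen, did not pass over all loci (adjusted p = 0.0649). The list was shifted upward at a camera adjusted p of 2.76e-07 (adjusted p = 0.580 with an estimated correlation). All 9 genes had a higher ratio in replicate 2 than in replicate 1, with list medians of 2.72 and 1.56. Without replicate 1 and without replicate 2, in that order, cbbL was at 4.34 and 2.999, cbbA at 3.89 and 2.66, cbbP at 3.81 and 1.56 and cbbT at 2.29 and 0.86. The call of cbbP was lost without the Cy3 array of replicate 1, where its log2 ratio was 2.70, and when arrays were scaled (2.92) or quantile normalized (2.68).

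**Figure D2:**
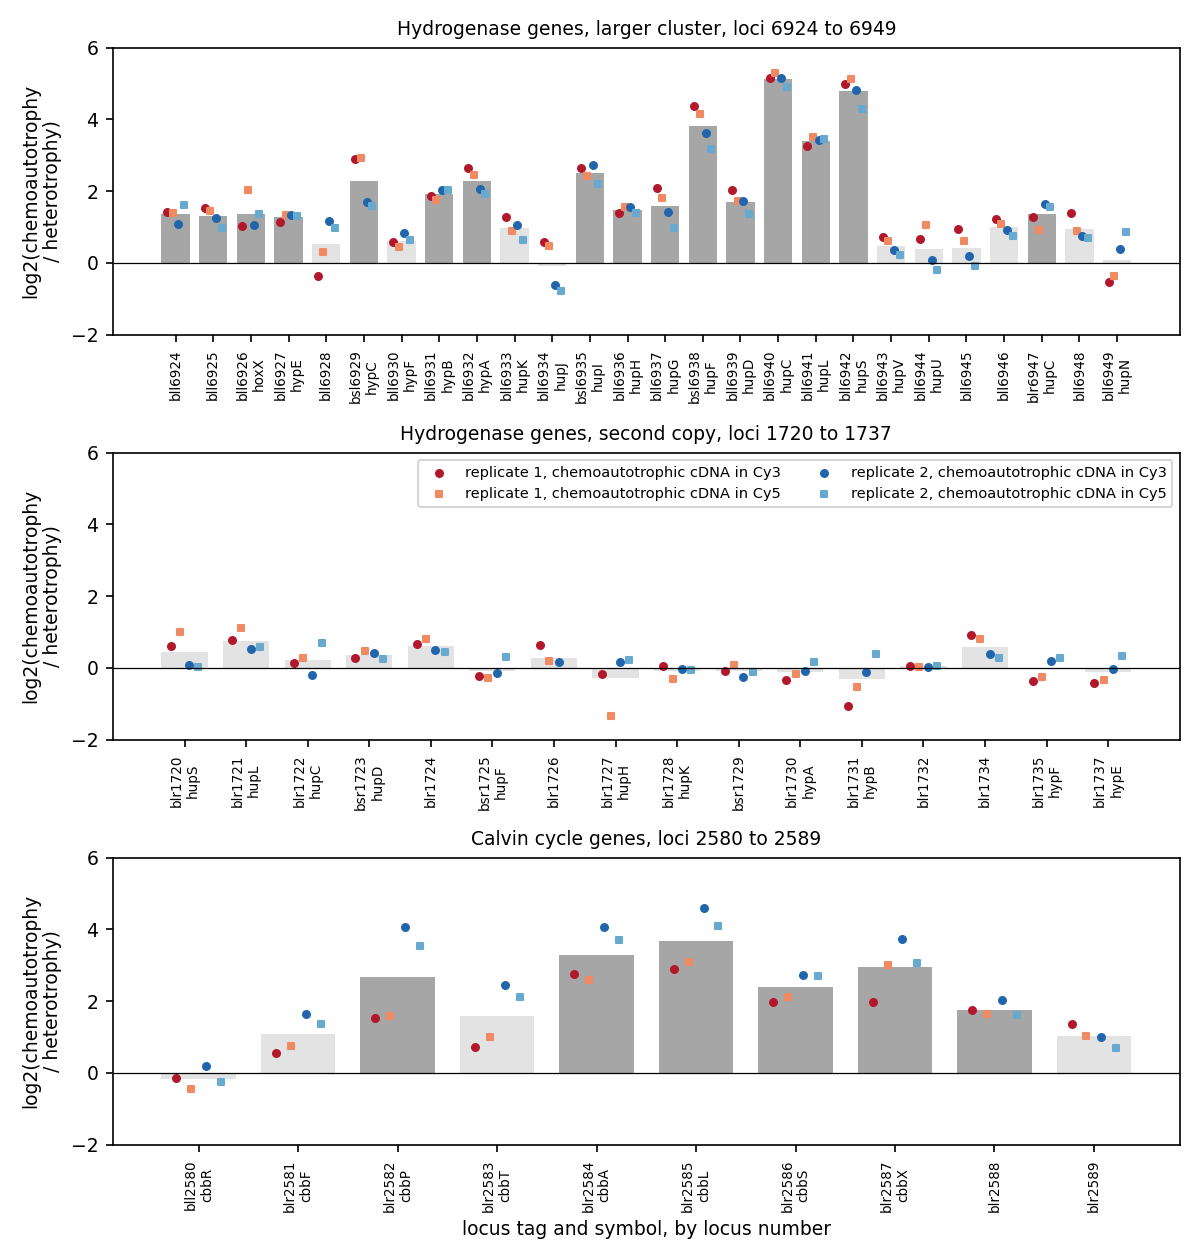
Log2 ratios of chemoautotrophy over heterotrophy (likely direction, y axis) for loci in order of their numbers (x axis), in the larger hydrogenase cluster, the second hydrogenase set and the Calvin cycle cluster. Bars are means of 2 replicates, dark where the locus passed the test, and points are the 4 arrays, coloured by replicate and shaped by dye orientation; hupC at bll6940 reaches 5.13, whereas the second set has 0 dark bars.

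Of 22 nitrogen fixation genes 5 rose and 0 fell, and 10 rose when adjusted over the list alone (limma; 10 members had an unadjusted p under 0.05). nifD (2.26 ± 0.30) and nifK (1.86 ± 0.23), for the subunits of the molybdenum-iron protein, and nifX (1.67 ± 0.24) rose 4.79-fold, 3.62-fold and 3.18-fold (n = 2). The other members to rise, named after their values were seen, were nifN (1.57) and nifR (1.51), whose tag, blr4486, lies close to ntrY (blr4489). nifR was matched by its symbol alone, and whether it belongs to nitrogen fixation was not tested. nifH (blr1769), for the iron protein of nitrogenase and also named after its value was seen, was at 0.81 ± 0.26 and did not pass over all loci (adjusted p = 0.153). The list's camera adjusted p was 0.000114 (adjusted p = 0.567 with an estimated correlation). The call of nifD was lost after quantile normalization. In the list of ammonium and nitrogen assimilation, 2 of 29 genes rose, over all loci and adjusted over the list alone. They were the genes of a regulatory pair, ntrX (2.55 ± 0.30) and ntrY (1.63 ± 0.29; n = 2), and ntrY differed by 0.75 between dye orientations. The list as a whole did not pass (camera adjusted p = 0.0629), and the call of ntrY was lost without the Cy3 array of either replicate (adjusted p 0.0511 and 0.0763).

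In the microaerobic respiration list 2 of 16 genes fell and 0 rose, both with the symbol fixK, at bll2757 and at bll3466 (-1.73 ± 0.24, 3.33-fold lower, n = 2). Adjusted over the list alone in limma, 5 were lower and 1 higher, and 7 members had an unadjusted p under 0.05. Besides fixN, the lower ones all had the symbol fixK (bll2757, bll3466, bll6061 and bll7696), and the higher was fixP. Those not named above were named after their values were seen. Whether the probes of the other fixK loci read transcripts of bll2757 was not tested. The list was shifted downward at a camera adjusted p of 0.0492 (adjusted p = 0.567 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0633), with ranks (0.153) and without the Cy5 array of replicate 1 (0.0535). The ratio of fixK at bll2757 differed by -0.89 between dye orientations and was negative on all 4 arrays.

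Other routes of respiration were mixed. Of 24 other cytochrome and oxidase genes 3 rose and 0 fell: coxB (1.82 ± 0.31) and coxA (1.53 ± 0.24), for subunits of a cytochrome oxidase, and cycA (1.69 ± 0.35), for a cytochrome c (n = 2). Calls were lost without the Cy3 array of replicate 1 (coxB 0.0555, cycA 0.0678, adjusted p) or of replicate 2 (cycA 0.0611) and after quantile normalization (coxA). cycA was at 1.02 without replicate 1 and at 2.36 without replicate 2. Adjusted over the list alone 3 were higher and 3 lower (limma; 8 members had an unadjusted p under 0.05). The list's camera adjusted p was 0.990, with a median of -0.11, a mean of 0.05 and a downward direction in the test. Of 18 denitrification genes 0 passed over all loci in limma, 5 had an unadjusted p under 0.05, and 2 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.990, with a median of -0.01, a mean of -0.03 and an upward direction in the test). Within it napB was at 1.57 ± 0.38 and napE at -1.35 ± 0.35 (adjusted p 0.0780 and 0.0938), both genes of periplasmic nitrate reductase. Both passed with the replicate block (limma adjusted p 0.0197 and 0.0216), also beside a dye term (0.0420 and 0.0481), with centred arrays (0.0116 and 0.0239) and without the Cy5 array of replicate 2 (0.0164 and 0.0245). Without replicate 1 and without replicate 2, in that order, napB was at 0.78 and 2.36 and napE at -2.04 and -0.66. Of 10 genes matched by symbol to the carbon monoxide dehydrogenase list, 1 rose over all loci and 2 were higher adjusted over the list alone. The list had a camera adjusted p of 0.736, a median of -0.06 and a mean of 0.16. The gene that rose over all loci was coxG (blr1174, 1.32 ± 0.23, n = 2). The other was coxE (blr1172, 1.12), named after its value was seen. Both lie close to coxB (blr1170) and coxA (blr1171) of the cytochrome oxidase, and whether they belong to carbon monoxide dehydrogenase was not tested. The call of coxG was lost without the Cy3 array of replicate 2 (limma adjusted p = 0.0553). The large subunit gene cutL stood at 0.37 ± 0.29 (blr3350), -0.10 ± 0.24 (blr3533) and -0.15 ± 0.25 (bll6237). Of the 6 cut genes, a split chosen after the values were seen, limma called 0, and 0 had an unadjusted p under 0.05.

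ATP synthase genes were higher as a list: 3 of 8 rose over all loci, 6 when adjusted over the list alone, and 0 fell (limma; 6 members had an unadjusted p under 0.05). atpB (bll1185, 2.19 ± 0.26), atpC (bsl1187, 1.98 ± 0.24) and atpA (bll1188, 1.53 ± 0.27) rose 4.58-fold, 3.95-fold and 2.89-fold (n = 2). These lie in a single stretch of tags. Another atpA (bll0442, 1.09), named after its value was seen, did not pass over all loci (limma adjusted p = 0.0604). All 8 ratios were positive (camera adjusted p = 5.51e-06, or 0.567 with an estimated correlation). The call of atpA at bll1188 was lost without the Cy3 array of replicate 1 (limma adjusted p = 0.0543). In central carbon metabolism limma called 0 members in each list, over all loci and adjusted over the list alone. The 8 glycolysis and gluconeogenesis genes, 1 of them at an unadjusted p under 0.05, had a camera adjusted p of 0.0492 and a median of 0.54 (adjusted p = 0.567 with an estimated correlation). That call was lost with centred arrays (0.0579), with ranks (0.0503) and without the Cy3 array of replicate 1 (0.0636) or of replicate 2 (0.0718). The list also did not pass with fry (0.0576), which tests a list by itself on all 4 arrays with the replicate block. Its largest ratios were gapA (0.67 ± 0.32; 1.26 without replicate 1 and 0.08 without replicate 2) and pgk (0.67 ± 0.28). The 14 genes of the tricarboxylic acid and glyoxylate cycles, 1 of them at an unadjusted p under 0.05, had a camera adjusted p of 0.458, with sdhA at 0.75 ± 0.26 and sdhD at 0.57 ± 0.25. For the 14 genes of NADH dehydrogenase, 0 of them at an unadjusted p under 0.05, it was 0.836, with nuoM at 0.52 ± 0.25 and nuoL at 0.34 ± 0.29. The 4 measured genes of the Entner-Doudoroff and pentose phosphate pathways, too few to test as a list and with 0 at an unadjusted p under 0.05, included tktB (0.43 ± 0.28) and rpiA (0.30 ± 0.25).

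Chaperone genes rose in 6 of 30 cases and fell in 0, and adjusted over the list alone 12 were higher and 3 lower (limma; 18 members had an unadjusted p under 0.05; camera adjusted p = 0.00197; adjusted p = 0.567 with an estimated correlation). groES (blr5625, 2.71 ± 0.33) and groEL (blr5626, 2.69 ± 0.23), which encode a chaperonin, rose 6.53-fold and 6.46-fold, and clpB (2.17 ± 0.24), for a protein disaggregase, 4.49-fold (n = 2). This groES was at 2.11 without replicate 1 and at 3.30 without replicate 2. The 3 members lower over the list alone, named after their values were seen, were hspE (-1.32), hspB (-1.16) and hspH (-0.95). The members of this list thus did not all move the same way. Several loci share the symbols groES and groEL, and how specific their probes are is not given in the sources used here. Of 53 ribosomal protein genes only rpsE (1.24 ± 0.23) and rplM (1.19 ± 0.23, n = 2) rose, 2 also when adjusted over the list alone, and 0 fell (limma; 22 had an unadjusted p under 0.05). The ribosomal list was shifted upward (camera adjusted p = 4.98e-07; adjusted p = 0.699 with an estimated correlation), with a median of 0.99 in replicate 1 and 0.13 in replicate 2. It did not pass with fry (adjusted p = 0.214). The calls of rpsE and rplM were lost after quantile normalization and without the Cy3 array of either replicate (adjusted p 0.0522 to 0.0702). Of 65 flagella and chemotaxis genes 4 rose and 0 fell, and 9 rose when adjusted over the list alone (limma; 14 had an unadjusted p under 0.05; camera adjusted p = 0.00266; adjusted p = 0.567 with an estimated correlation). They were the response regulator gene cheY (2.13 ± 0.29), fliL (1.51 ± 0.26), the flagellin gene fla (1.31 ± 0.23) and, named after its value was seen, fliN (1.15), with n = 2. The call of fliL was lost without the Cy3 array of either replicate (adjusted p 0.0522 and 0.0528), and that of fla after quantile normalization. The median of the flagella and chemotaxis list was 0.13, with 0.06 in replicate 1 and 0.24 in replicate 2. Of its 65 ratios 36 were positive in replicate 1 and 49 in replicate 2.

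**Figure D3:**
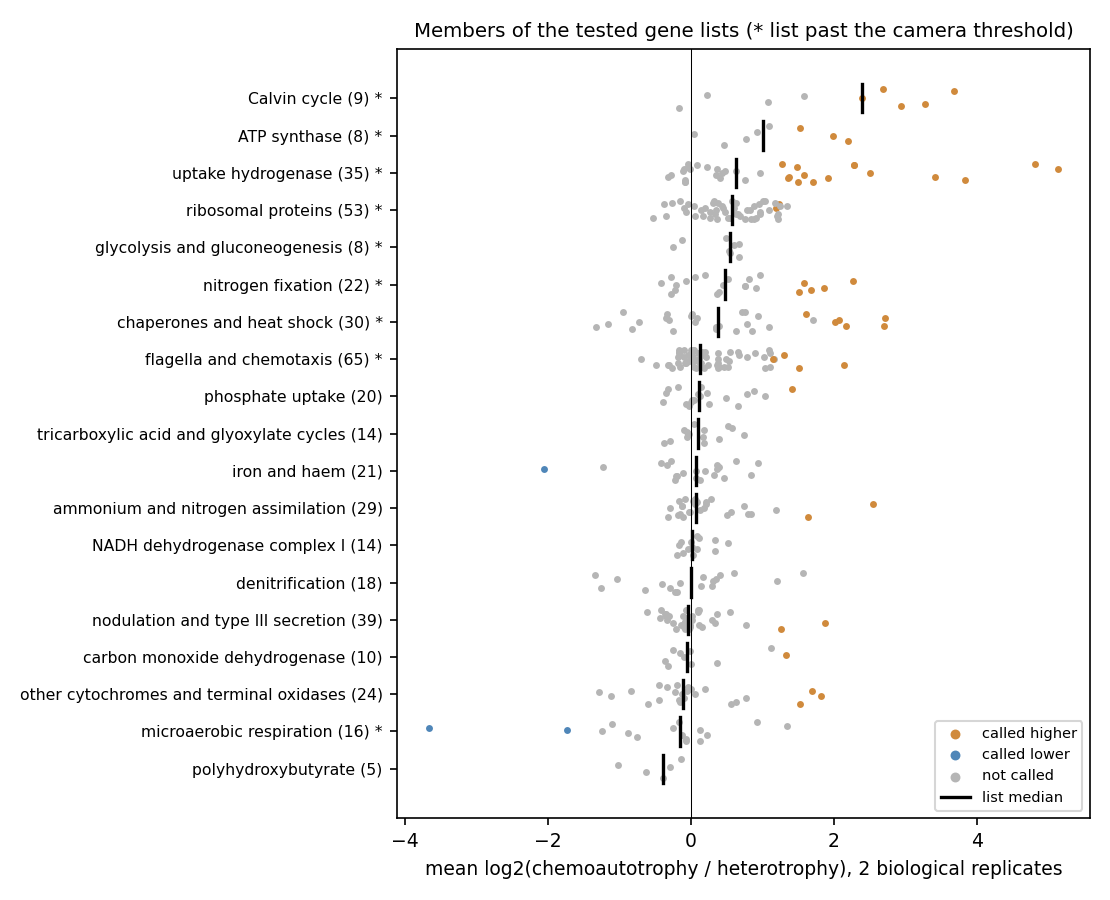
Mean log2 ratio of chemoautotrophy over heterotrophy (likely direction, x axis, 2 replicates) of each member of the 19 tested gene lists (y axis, with the number measured), 1 point per locus. Black bars are list medians and asterisks mark the 9 lists that passed camera with the preset correlation. With an estimated one, which leaves 1 residual degree of freedom, 0 passed.

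The remaining lists did not pass as lists. Of 39 nodulation and secretion genes 2 rose, over all loci and adjusted over the list alone: nodA (1.87 ± 0.34), for a step of Nod factor synthesis, and nodQ (bll1475, 1.25 ± 0.23; n = 2), with a camera adjusted p of 0.990 for the list (median -0.04, mean 0.04, downward in the test). nodQ lies in a stretch from bll1475 to blr1482, on both strands, in which 6 loci rose. With it rose cysD (1.23 ± 0.23), both for sulfate activation, blr1478 (1.44 ± 0.27), blr1479 (2.84 ± 0.32), blr1480 (1.71 ± 0.25) and blr1482 (2.03 ± 0.25). Between them blr1477 (1.01 ± 0.23) and cysH (blr1481, 1.32 ± 0.28), both named after their values were seen, did not pass (adjusted p 0.0659 and 0.0552). The calls of nodQ and cysD were lost after quantile normalization and without the Cy3 array of either replicate, that of nodA without the Cy3 array of either replicate, and that of nodQ also with the replicate block (adjusted p = 0.0763). Without either array these adjusted p ran from 0.0522 to 0.158. Without replicate 1 nodA was at 1.24, and without replicate 2 at 2.51. The call of blr1478 was lost after scaling and after quantile normalization, and that of blr1480 after quantile normalization. Of 20 phosphate uptake genes the gene of the phosphate-binding protein, pstS, rose (1.41 ± 0.24, n = 2), also when adjusted over the list alone (camera adjusted p = 0.121), though not after quantile normalization. Of 21 iron and haem genes hemA fell (-2.06 ± 0.38, n = 2), which encodes the first enzyme of haem synthesis, also when adjusted over the list alone (camera adjusted p = 0.876; median 0.07, mean -0.01).

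Of 5 polyhydroxybutyrate genes limma called 0, over all loci and adjusted over the list alone, and 2 had an unadjusted p under 0.05. phbC was at -1.02 ± 0.34 and phbA at -0.62 ± 0.23, both for enzymes of the synthesis of this storage polymer (camera adjusted p = 0.0550 for the list), with phbC at -1.66 without replicate 1 and at -0.39 without replicate 2. The list passed with ranks (adjusted p = 0.0356) and without the Cy3 array of replicate 1 (0.0499). Lists with under 5 members were not tested. Of 4 oxidative stress genes limma called 0 over all loci and 1 was higher adjusted over the list alone, with 2 at an unadjusted p under 0.05. Their largest ratios were ahpC (1.07 ± 0.26) and ahpD (-0.67 ± 0.23). ahpC passed with the replicate block (limma adjusted p = 0.0191), also beside a dye term (0.0394), with centred arrays (0.0215) and without the Cy5 array of replicate 2 (0.0212). Of 2 carbonic anhydrase genes limma called 0 over all loci, with 1 at an unadjusted p under 0.05. The copy of cah at bll1137 (0.99 ± 0.23) was higher adjusted over the list alone, and cah at blr0500 was at 0.13 ± 0.24. The former passed over all loci with the replicate block (limma adjusted p = 0.0141), also beside a dye term (0.0299), with centred arrays (0.0263) and without the Cy5 array of replicate 2 (0.0166). Of 3 genes for the oxidation of 1-carbon compounds limma called 0, with 0 at an unadjusted p under 0.05, and fdhF was at -0.29 ± 0.23 and fdhD at -0.12 ± 0.23.

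Further genes with a symbol fell. The biotin synthase gene bioB (blr2095) fell 7.75-fold (-2.95 ± 0.25) and its neighbour panD (blr2096), for an enzyme of pantothenate synthesis, 6.74-fold (-2.75 ± 0.28; n = 2, limma adjusted p 0.00423 and 0.00631). exaA, for an alcohol dehydrogenase, fell to a log2 ratio of -2.32 ± 0.33, mdcA, for a malonate decarboxylase subunit, to -1.86 ± 0.28 and dop to -1.74 ± 0.26, with n = 2. Outside the lists, the ribonucleotide reductase gene nrdE rose 7.47-fold (2.90 ± 0.32, n = 2). Among loci known by tag only, bll7411 fell 52.3-fold (-5.71 ± 0.26) and blr0305 32.6-fold (-5.03 ± 0.28), while blr2455 rose 23.9-fold (4.58 ± 0.30) and blr4700 12.6-fold (3.65 ± 0.62; n = 2). Without replicate 1 and without replicate 2, in that order, blr4700 was at 2.18 and 5.12, exaA at -2.92 and -1.72, and hemA at -2.85 and -1.27. The call of blr4700 was lost without the Cy3 array of replicate 1 (adjusted p = 0.0577). hemA lost its call without that array (0.0751), after scaling and after quantile normalization.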

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

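The tests in this part were chosen after the results were seen. The 2 dye orientations should give the same ratio once the sign of 1 of them is turned, and 27 of 7918 loci differed between them (limma, paired within replicates; 777 had an unadjusted p under 0.05). The ratio was higher with chemoautotrophic cDNA in Cy3 at 20 of these and in Cy5 at 7. Of the 27 loci 3 had changed between the growth conditions, and 2 of those are named in the report: fixK at bll2757, with a Cy3 minus Cy5 difference of -0.89 (limma adjusted p = 0.0497), and ntrY at blr4489, with a difference of 0.75 (limma adjusted p = 0.0456).

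The low ratio of fixK at bll2757 was weighed against 3 technical explanations. Dye bias is argued against as the whole cause, since the array closest to 0 still gave -2.95. Cross-hybridisation with another locus of the symbol fixK is argued against because the lowest of the other 4 was at -1.73, although transcripts without that symbol were not examined. A drop of all neighbours with higher locus numbers is argued against by a median of -0.16 over the 13 loci from bll2758 to bsr2770. These ranged from -2.07 (bll2758, which also fell) to 1.35. Neighbours with lower numbers were not part of this comparison, and bll2758 lies next to bll2757 on the same strand by its tag. A drop of a shorter stretch, or of one that extends to lower numbers, was therefore not tested. A change of fixK transcripts with the growth condition, in a direction that is itself only likely, stays open as a hypothesis, since it was found and tested on the same data.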

How the results depend on the processing

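Alternatives were set before the data were examined, except the splits of the hydrogenase and carbon monoxide dehydrogenase lists, the list medians per replicate and the count of loci 2-fold changed in both replicates (370). The 358 changed loci (195 higher, 163 lower) became 981 with the replicate block (550, 431), 735 with the replicate block and a dye term (397, 338) and 1989 with 4 arrays taken as independent (1120, 869); these fits take the technical arrays as further observations. Centring each array gave 749 (437, 312), an adjusted p under 0.01 gave 100 (51, 49), under 0.1 gave 677 (373, 304), a 2-fold minimum with 1 sign and no test gave 684 (384, 300), and limma's treat against 1.5-fold gave 118 (62, 56). Without 1 array the count ran from 234 (Cy3, replicate 1) to 916 (Cy5, replicate 2), from 128 to 534 higher and from 106 to 382 lower; why centring and left-out arrays move it this far was not tested. Scaled arrays gave 343, quantile normalization 265, robust moderation 358, and loci measured on all 4 arrays 381. With the sign of replicate 2 turned limma called 0 loci (0 higher, 0 lower; 23 at an unadjusted p under 0.05); this moves shared changes into the residual spread, so it is no count of false calls. With no array turned it called 10 (8 higher, 2 lower). Under the fits, scalings, filters and left-out arrays computed for each locus named by the rule, none changed sign. In single replicates, 5 that had not passed did (cutL at blr3350, blr3533 and bll6237, nuoL, and cah at blr0500), 0 of the 62 that had passed did, and 10 of the 62 moved by over 1.5-fold, as did napB, napE, phbC and gapA, which had not passed, all as given in the report; turning the other dye orientation mirrors all of them, and single loci were not followed with no array turned or with the sign of replicate 2 turned. Of 62 named calls, 14 were lost without the Cy3 array of replicate 1, 11 without that of replicate 2, 13 with quantile normalization, 3 with scaling, 1 (nodQ) with the replicate block, also beside a dye term, and 0 with robust moderation. Named loci that had not passed gained calls: 5 with the replicate block (napB, napE, ahpC, cah at bll1137 and hupL at blr1721), 4 of these with the dye term, with centring and without the Cy5 array of replicate 2 (without hupL), and 10 with 4 independent arrays. Of the 9 lists that passed camera, 0 did with an estimated correlation, where 1 residual degree of freedom is left, too few to decide on a list. The replicate block ended the call of the microaerobic list (adjusted p = 0.0633) and of no other list. With fry, which does not compare a list with other loci, the ribosomal list had an adjusted p of 0.214, glycolysis 0.0576 and polyhydroxybutyrate 0.010; the last was also past the threshold with ranks (0.0356) and without the Cy3 array of replicate 1 (0.0499). An intensity trend was not run, since no intensities were used here, nor were lists by product name. Without intensities, the signal over background behind a ratio is unknown.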

Other observations

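All tests in this part were chosen after the results were seen. Further stretches held several loci changed the same way, at times with a locus that did not pass between them, and are named after their values were seen. Between bll1438 and blr1444 4 loci rose by 1.41 to 2.73 on the log2 scale, ctpE, ctpC, ctpA and blr1444. Between blr3677 and blr3681 4 loci without a symbol fell, at -4.02 to -2.59, and from bll6205 to blr6208 4 loci including exaA fell, at -2.41 to -1.34. bioB and panD fell with bioD close by, and further copies of groES and groEL rose, groES at blr6978 by 2.07 and, between blr7530 and blr7533, groES and groEL by up to 2.02.

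Loci that lie next to each other had similar ratios. Strands were read from the letter l or r in the locus tags. Across 5338 pairs of neighbours on the same strand the log2 ratios correlated at r = 0.453 (Spearman's rho 0.406), and across 2607 pairs on opposite strands at r = 0.137 (rho 0.146), pairs of loci not being independent replicates. The highest r of 100000 random pairings was 0.058 (permutation test, p = 1e-05, the smallest these permutations can give), and exchanging the strands of pairs gave a difference as large with p = 1e-05, again the smallest possible. The higher correlation on the same strand could reflect co-transcription of neighbours, as a hypothesis, since no transcript boundaries were used here. Co-transcription does not cover the r of 0.137 between neighbours on opposite strands, and the source of that similarity was not tested.

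The hydrogenase genes come in 2 sets, and in 11 of 11 symbols present in both, the copy in the larger cluster had the higher ratio, by 2.43 ± 1.41 (SD over the 11 pairs). The difference was not tested, since the pairs were chosen after the ratios of both sets were seen and genes of a cluster are not independent. The highest ratio in the second set was 0.76. Whether the probes of the 2 sets read each other's transcripts was not tested.

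At 7 loci the replicates changed at least 2-fold in opposite directions, against 370 in the same direction. Among the 7 were tspO (3.48 in replicate 1, -1.44 in replicate 2), blr2476 (4.16, -1.29) and norC (-2.67, 1.37), for a subunit of nitric oxide reductase. Noise of single hybridisations is argued against, since the dye-exchanged arrays differed by a median of 0.22 at these loci and the replicates by 3.88. Different centring is argued against by a gap of 0.11 between the medians of the replicates. A difference between the 2 pairs of cultures stays open, and no biological explanation was tested.

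Ribosomal protein genes were higher in replicate 1 than in replicate 2 in 48 of 53 cases, with a gap of 0.86 between the list medians. Of 10000 random lists of the same size, not matched on expression, 0 had a gap as large (highest 0.26). Genes of such a list may move together, unlike loci drawn at random, so that count gives no probability for the gap. The list's estimated correlation of 0.65 rests on 1 residual degree of freedom. It restates the 48 of 53 cases and is no separate evidence that members move together. Centring is argued against, since the gap was 0.96 after it, and so is a single hybridisation, since the lower array of replicate 1 lay 0.73 above the higher of replicate 2, against at most 0.14 between arrays of a dye exchange. A bias in the normalization of abundant transcripts cannot be told apart from a difference between cultures, because abundance was not measured here; the ATP synthase list had a gap of 0.18. A difference in growth between the cultures may also be involved and was not tested.

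The 8 measured genes from fixN to fixS, which encode a high-affinity oxidase and its assembly proteins and are known targets of FixK proteins in this genus, ranged from -1.24 (fixN) to 1.35 (fixP), and limma called 0 of them over all loci, with 3 at an unadjusted p under 0.05. Adjusted over the microaerobic list alone, fixP was higher and fixN lower (limma adjusted p = 0.0117 for each).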
